A study of Arabidopsis thaliana with 45 samples.

How the data were processed

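The series holds 45 Arabidopsis thaliana libraries: 12 of RNA (4 genotypes, 3 libraries each, aerial part of 2-week-old seedlings), 27 of H3K27me3 ChIP (9 groups of 3) and 6 of H3K9me2 ChIP (2 groups of 3). Groups and replicate numbers were taken from the labels, and 0 columns stayed unmapped. The wild type, amiR-fie-es, GFP-FIE and SSTS/AAAA lines are 2-week-old plants. The tor-es and Col-0 seedlings and those given DMSO, AZD8055 or Torin2 are 7 days old and grown in liquid medium. Per the labels, oestradiol (10 mM as written there) was given to amiR-fie-es from the start and to tor-es on the third day, and 10 µM inhibitor or DMSO was added on day 4 for 3 days. The labels do not say whether the wild-type groups received oestradiol, so the effect of the inducer is not separated from that of the silenced gene.

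Per the submitters' processing notes, RNA reads were checked with FastQC 0.11.5, trimmed with Trimmomatic 0.36, aligned to TAIR10 with HISAT2 2.1.0 and counted per gene with featureCounts of Subread 1.5.3. The deposited values are raw counts, whole numbers that the authors had not normalized; the strand setting and the rule for reads with several matches are not stated, so genes with near-identical copies, overlapping genes and antisense pairs are uncertain. The FPKM table of the same libraries was not used here. Per the same notes, ChIP reads were trimmed with Trimmomatic 0.36, aligned with BWA 0.7.15-r1142, handled with SAMtools 1.6, and peaks were called with MACS2, whose version is not given in the sources used here. Builds TAIR10 and hg19 are named for them; the peak lists hold 0 peaks on human chromosomes. Each deposited peak list belongs to 1 library and gives per peak a score, a fold enrichment ratio at the summit over local background, and −log10 p and −log10 q values, as the authors' MACS2 wrote them. Input controls, duplicate handling and the q threshold are not stated, and read depth is unknown from these lists. Peak start positions were converted to 1-based coordinates of TAIR10.

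Gene names came from a reference table of assembly TAIR10.1, which matched 31912 of 32678 gene IDs. The same table placed 27215 nuclear protein-coding genes and 3890 pseudogenes against the peaks, after a check that the coordinates of both builds line up. With no shift, 4913 genes were marked in all 3 Ctrl libraries and 394 were covered over at least 90% of their length; with shifts of 1 to 20 kb, 3442 to 4125 and 59 to 94 were. No gene coordinate from that table is printed.

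Differential expression used edgeR 4.0.16 in R 4.3.3: filterByExpr defaults (20046 genes tested), TMM normalization, 1 fit of all 12 libraries by group without covariates, the quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05, two-sided. Every adjusted p printed for a gene comes from that test. Total counts per library ran from 28866845 to 34543091, the group means of CPM carry no prior count, and where the lower group held 1 to 3 counts a ratio with its 95% counting interval is given; such intervals cover counting error only. The difference of effects is the contrast of SSTS/AAAA minus GFP-FIE against amiR-fie-es minus Ctrl. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 15 lists. The lists were floral organ and flowering-time, meristem with boundary and homeobox, embryo and seed regulators, seed storage, photosynthesis, ribosomal proteins, sugar starvation, cell cycle, defence and stress, TOR pathway, PRC2 subunits, PRC1 and H3K27me3 readers, H3K27 demethylases, root markers and pollen markers. They hold 170 genes in all; 2 list entries were dropped because their symbol and ID disagreed in the reference table. The floral, seed, root and pollen lists were also meant to stand for tissue that shoots of this age should hold little of. Some members were nevertheless well expressed in Ctrl, such as SVP of the floral list (90.2 CPM) and SCR of the root list (64.2 CPM).

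A gene counted as marked when the peaks of a library covered at least 200 bp of it. Loss means marked in 3 of 3 control and 0 of 3 case libraries, and gain the reverse. Covered length is the union of a library's peaks on the 5 nuclear chromosomes, compared as a ratio of geometric means with an exact permutation test of 3 against 3 libraries, two-sided, whose smallest p is 0.1; its 90% interval is the range of ratios between single libraries. Covered length moves with how much was called, so peak lists of different experiments were set against each other only for genes that lost the mark and for peaks over the genes with the highest RNA, where the experiment and how much was called are not separated. Overlaps used Fisher's exact test, one-sided for excess, among genes that could enter both lists; for the inhibitors, which share DMSO libraries, 200 simulations of unchanged groups stand beside it. Losses were set against RNA with Fisher's exact test, two-sided. Bins of 1 Mb were called H3K9me2-rich when in the top 10% by H3K9me2 length in Col-0, and those with the least H3K27me3 are the lowest 10% by H3K27me3 length in Ctrl. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these.

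Lists, tests, thresholds and the rule for named genes were fixed before the data were examined, as were all alternatives except those that the text here or the part on how the results depend on the processing says were chosen after seeing the data. By that rule the text names FIE, the 10 higher and 10 lower genes with the largest log2 fold change per RNA comparison (adjusted p under 0.05, at least 5 CPM in the higher group, libraries of the groups not overlapping), and up to 4 members per list. It also names up to 10 genes per ChIP comparison with the longest lost or gained mark, list members that lost or gained it, FIE, TOR, FLC, AG and STM, and the 10 genes with the largest rise among those that lost the mark. Further list members, and the genes of the closing section, are named as examples chosen after their values were seen. Control peaks over the 100 genes with the highest Ctrl RNA were compared with other peaks of the same library in the same of 20 classes of −log10 q and 3 of width, by the share of their length that another library covers. The code was tested on simulated data. Of 50 genes changed 2-fold, 48 were recovered for amiR-fie-es against Ctrl, 46 for SSTS/AAAA against GFP-FIE and 48 for GFP-FIE against Ctrl, with 23, 18 and 16 false calls among 19822, 19797 and 19827 genes; of 50 changed 1.5-fold, 40, 43 and 38. The peak code recovered 50 of 50 simulated losses and 30 of 30 gains. Alternatives covered normalization, low-count filters, DESeq2 1.42.0, replicate blocks, peak thresholds, overlap rules and leaving out each library.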

Results

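Polycomb repressive complex 2 (PRC2) places trimethylation on lysine 27 of histone H3 (H3K27me3), a mark of silenced genes, and FIE is its WD40-repeat subunit. The TOR kinase couples nutrient status to growth, and the series asks how TOR and FIE bear on this mark and on gene expression in Arabidopsis thaliana. The 45 libraries fall into 15 groups of 3. RNA sequencing covered the aerial part of 2-week-old seedlings of 4 genotypes. These were the wild type Col-0 (Ctrl), amiR-fie-es (an oestradiol-induced artificial microRNA against FIE), GFP-FIE (the fie mutant complemented with GFP-tagged FIE) and SSTS/AAAA (the fie mutant with a tagged FIE whose name gives serines and a threonine replaced by alanine). H3K27me3 ChIP sequencing covered the same 4 genotypes. In 7-day-old seedlings, H3K27me3 was profiled in Col-0, in tor-es (oestradiol-induced silencing of TOR), and in seedlings given DMSO, AZD8055 or Torin2, and H3K9me2 was profiled in Col-0 and tor-es. Total counts ran from 28866845 to 34543091 per RNA library. Read depth of the ChIP libraries is unknown from their peak lists, which hold 221891 peaks.

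The comparison of amiR-fie-es with Ctrl asks what lower FIE does to gene expression. FIE transcript fell in amiR-fie-es to 0.507 of Ctrl (log2 fold change -0.98 ± 0.07 SE, n = 3 per group, edgeR adjusted p = 4.06e-16). FIE stood at 8.79 to 9.10 CPM (normalised read counts) in its 3 libraries, against 15.7 to 18.6 in Ctrl. Genes that specify floral organs and the transition to flowering rose in these shoots. The labels do not say whether the shoots had begun to flower. FT, the mobile flowering signal, rose from 0.145 to 17.6 CPM (log2 fold change 6.88 ± 0.17, adjusted p = 6.73e-33), and AG, which specifies stamens and carpels, rose from 0.352 to 35.2 CPM (6.63 ± 0.14, adjusted p = 3.19e-35). AP3 rose from 0.0486 to 7.98 CPM, PI from 1.15 to 28.7 and SEP3 from 3.11 to 96.3.

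Of the 24 measured genes in the floral organ and flowering-time list, 20 rose in amiR-fie-es and 3 fell, the same numbers when adjusted over the list alone (camera adjusted p = 1.96e-06, and adjusted p = 0.00672 with an estimated correlation). Their median log2 fold change was 2.14. AGL17 had 1 count in the 3 Ctrl libraries together, for a ratio of 401 (95% counting interval 71.7 to 15882). FLC, the floral repressor, rose from 1.55 to 7.08 CPM, while the repressor SVP fell from 90.2 to 42.3 CPM and MAF5 from 5.13 to 1.49. All 23 nuclear photosynthesis genes fell, with a median log2 fold change of -0.46 (camera adjusted p = 2.51e-13), RBCS2B at -0.85, RBCS1B at -0.68 and LHCB2.1 at -0.29. That call was lost with an estimated correlation (adjusted p = 0.205). Chloroplast-encoded genes took 0.780% to 0.824% of the counts in amiR-fie-es and 1.01% to 1.09% in Ctrl. Members of the RBCS and LHCB families share sequence, so their separate values are uncertain.

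**Figure D1:**
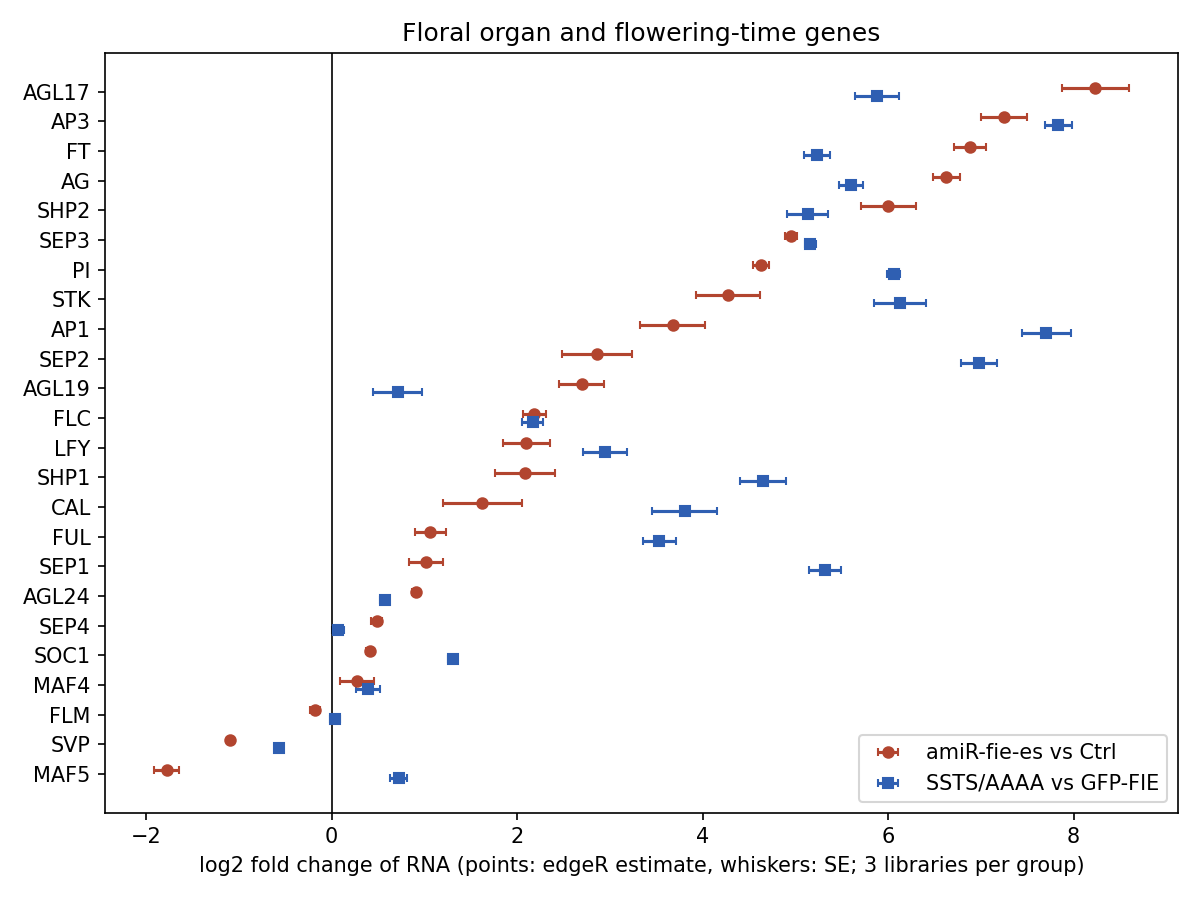
Log2 fold changes of RNA for the 24 measured floral organ and flowering-time genes, in amiR-fie-es against Ctrl (circles) and SSTS/AAAA against GFP-FIE (squares); whiskers are SE, with 3 libraries per group. AP3 stands at 7.25 and 7.83, AG at 6.63 and 5.60, and SVP at -1.09 and -0.57.

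Beyond these lists, the genes with the largest rises in amiR-fie-es included SVL3, at 9.15 against 0.0482 CPM, CKX3, a cytokinin oxidase (7.74 against 0.0486 CPM), HB40, a homeodomain factor (8.20 against 0.0603 CPM), CER4, a fatty acyl reductase of wax synthesis (5.16 against 0.109 CPM), AT1G03710 (log2 fold change 6.07 ± 0.14) and FTM1 (5.03 ± 0.13). TLP5, a tubby-like protein, had 2 counts in Ctrl, for a ratio of 273 (95% counting interval 75.3 to 2259). LEA7, a late embryogenesis abundant protein, fell from 160 to 0.206 CPM (log2 fold change -9.59 ± 0.10, adjusted p = 6.52e-47) and LTI65, a gene known to respond to abscisic acid and low temperature, from 154 to 0.334 CPM (-8.84 ± 0.09, adjusted p = 2.25e-47). On the log2 scale AT3G17520 (-10.28), AT3G27250 (-7.61), HSFA6A (-7.05), AT2G37870 (-6.99), TSPO (-6.93), AT3G02480 (-6.34), AT5G50360 (-6.28) and GolS2, a galactinol synthase (-6.15), fell as well. LEA7, LTI65, AT3G17520, TSPO and HSFA6A were also among the largest falls in GFP-FIE against the same Ctrl libraries. Against GFP-FIE in place of Ctrl, a comparison chosen after seeing the data, 622 of the 929 genes that rose at least 2-fold also rose at least 2-fold, and 576 of the 1053 that fell also fell.

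The other lists divided in amiR-fie-es, and camera called none of them. Of 12 defence and stress genes, 3 rose, among them VSP1 (log2 fold change 4.08) and PR5 (1.18), and 6 fell, among them the dehydrin RAB18, from 263 to 25.5 CPM, COR15A (-3.06), KIN1 (-2.78) and WRKY70 (-2.46) (adjusted p = 0.364). RAB18, KIN1 and WRKY70 were low in GFP-FIE too, at 21.5, 0.0841 and 11.8 CPM, so their fall was not particular to the line with less FIE. COR15A stood at 11.0 CPM in GFP-FIE and 10.7 in Ctrl. Of 4 sugar-starvation genes, 3 rose, with SEN1 from 32.0 to 88.1 CPM and the asparagine synthetase ASN1 from 131 to 348 CPM, and SEN5 fell (adjusted p = 0.0786). Of 5 PRC1 and H3K27me3 reader genes, 3 rose, with EMF1 from 35.8 to 61.4 CPM (adjusted p = 0.0949). Of 9 PRC2 subunit genes, 4 rose and 2 fell (adjusted p = 0.552): MEA, a histone methyltransferase, had 2 counts in Ctrl, for a ratio of 60.3 (95% counting interval 16.4 to 503), and SWN and MSI1 rose by 0.20 and 0.25 on the log2 scale. Of 14 meristem and boundary genes, 3 rose, STM among them at a log2 fold change of 0.23, and 2 fell, WOX1 at -1.10 and YAB5 at -0.75 (adjusted p = 0.802). Among 11 cell cycle genes 5 rose, PCNA1 among them at 0.46, and 2 fell (adjusted p = 0.370), among 7 ribosomal protein genes 4 rose and 0 fell (adjusted p = 0.370), and among 5 TOR pathway genes S6K2 rose by 0.49 and 2 fell (adjusted p = 0.886). Of 5 demethylase genes, REF6 rose by 0.18 and JMJ13 fell by 0.59 on the log2 scale (adjusted p = 0.802). Both measured embryo regulators, AGL15 and WOX2, fell (adjusted p = 0.364). The few measured markers of root, pollen and seed did not rise, unlike the floral genes above. Of 3 root genes measured among 11 listed, 2 fell (adjusted p = 0.364). Of 2 pollen genes among 6, 1 fell (adjusted p = 0.802), and of 2 seed storage genes among 14, 0 passed (adjusted p = 0.984). The counts were the same when adjusted over the list alone. Of 20046 genes tested, 5868 rose and 6005 fell, of which 929 and 1053 by at least 2-fold.

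The comparison of SSTS/AAAA with GFP-FIE asks what the phosphosite residues of FIE do, in a shared mutant background and with a shared tag. FIE transcript itself was lower in SSTS/AAAA, at 11.4 to 12.2 CPM against 23.8 to 27.6 in GFP-FIE (log2 fold change -1.11 ± 0.06 SE, n = 3 per group, edgeR adjusted p = 8.28e-20), so the lines differ in FIE level as well as in its residues. Floral organ genes rose again. AP3 rose from 0.156 to 36.7 CPM (log2 fold change 7.83 ± 0.14, adjusted p = 8.63e-38), AP1 from 0.0481 to 10.9, SEP2 from 0.135 to 17.3, PI from 1.29 to 86.3, SEP3 from 3.28 to 118, AG from 0.625 to 30.5 and FT from 0.421 to 16.1. STM and KNAT1, homeobox genes that keep shoot meristems undifferentiated, rose from 4.82 to 16.5 and from 7.14 to 23.2 CPM.

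Of the 24 measured floral genes, 21 rose in SSTS/AAAA and 1, SVP, fell (camera adjusted p = 3.50e-08, and adjusted p = 0.00282 with an estimated correlation), with a median log2 fold change of 4.23. FLC rose from 2.41 to 10.8 CPM, LFY by 2.95 and FUL by 3.53 on the log2 scale. Of 14 meristem, boundary and homeobox genes, 11 rose and 2 fell (adjusted p = 0.00344, and adjusted p = 0.0585 with an estimated correlation), with log2 fold changes of WOX3 at 4.43, CUC3 at 2.48, CUC1 at 2.46 and WOX1 at -1.12. All 23 photosynthesis genes fell, with a median of -0.47 (adjusted p = 4.11e-12, and adjusted p = 0.125 with an estimated correlation), RBCS1B at -1.03 and RBCS1A at -0.64. All 7 ribosomal protein genes fell, with RPS18A from 120 to 82.9 CPM and RPS6B at -0.33 (adjusted p = 0.000291, and adjusted p = 0.125 with an estimated correlation). Chloroplast-encoded genes took 0.698% to 0.914% of the counts in SSTS/AAAA and 1.03% to 1.12% in GFP-FIE. SSTS/AAAA replicate 1 stood apart in mitochondrial-encoded genes, at 0.0244% of counts against 0.0154% to 0.0182% in the other 11 libraries.

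All 4 sugar-starvation genes rose in SSTS/AAAA, SEN1 from 41.2 to 317 CPM and ASN1 from 254 to 932 CPM (adjusted p = 0.0153, and adjusted p = 0.235 with an estimated correlation). All 5 PRC1 and reader genes rose, EMF1 from 36.6 to 100.3 CPM and BMI1A by 0.14 on the log2 scale (adjusted p = 0.0470, and adjusted p = 0.130 with an estimated correlation). Of 9 PRC2 genes 5 rose, with log2 fold changes of MEA at 4.07 and SWN at 0.40, and 3 fell, with CLF at -0.23 and VRN5 at -0.30 (adjusted p = 0.831). Of 12 defence genes 7 rose, including PR2 (5.93), PR1 (4.67), VSP1 (3.43) and KIN1 (3.12), and 5 fell, including RD29A (-3.22), PR5 (-1.91) and COR15A (-1.89) (adjusted p = 0.408). Of 11 cell cycle genes 7 fell, CYCD3;1 at -0.44 and KNOLLE at -0.43 among them, and CDKB2;1 rose by 0.19 (adjusted p = 0.0753). Of 5 TOR pathway genes 4 rose, S6K2 by 1.19 and TOR by 0.16, and 1 fell (adjusted p = 0.147). Both measured seed storage genes rose, CRA1 by 3.24 and OLEO4 by 0.56 (adjusted p = 0.264). JMJ13 fell by 0.75 on the log2 scale, alone among 5 demethylases (adjusted p = 0.831), and of the embryo regulators AGL15 fell by 1.3 and WOX2 rose by 0.43 (adjusted p = 0.848). Of 3 root genes 2 fell, SHR among them (adjusted p = 0.432), and of 2 pollen genes RALF19 fell by 2.15 (adjusted p = 0.848). The counts were the same when adjusted over the list alone.

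Outside the lists, AT5G22430 rose from 0.109 to 43.8 CPM, the lipid transfer protein LTP4 from 0.0477 to 17.6 (with 43.4 in Ctrl, so that GFP-FIE stood apart), CYP714A1, a cytochrome P450 that inactivates gibberellins, from 0.0592 to 8.77, SVL3 from 0.119 to 15.3, and AT5G60140 by 6.81 ± 0.24 on the log2 scale. AT5G44630 had 2 counts in GFP-FIE, for a ratio of 274 (95% counting interval 75.5 to 2266), and AT1G66290 had 3, for a ratio of 140 (47.6 to 681). A run of neighbouring genes on chromosome 4 was nearly silent in SSTS/AAAA: AT4G22485 fell from 463 to 1.71 CPM (log2 fold change -8.07 ± 0.05, adjusted p = 1.90e-55), AT4G22505 from 461 to 1.54 (-8.22 ± 0.05, adjusted p = 2.66e-56) and AT4G22490 from 111 to 0.830, and AT4G22513 and AT4G22517 were also among the 10 largest falls. How reads with several matches were counted is not stated, so the values of single members of this run are uncertain. CDEF1, a cutinase, fell from 146 to 0.893 CPM, AT3G05727 from 121 to 0.534, AT5G38940 from 16.0 to 0.0558 and PRB1, a pathogenesis-related protein, from 7.07 to 0.0380. AT4G35810 kept 3 counts in SSTS/AAAA, for a ratio of GFP-FIE to SSTS/AAAA of 180 (95% counting interval 61.3 to 878). In all, 6666 genes rose and 6471 fell, of which 1534 and 951 by at least 2-fold. Against Ctrl in place of GFP-FIE, a comparison chosen after seeing the data, 1180 of those 1534 also rose at least 2-fold and 31, LTP4 among them, fell at least 2-fold, and 761 of the 951 also fell. KIN1 and RAB18, which rose against GFP-FIE, fell against Ctrl (log2 fold changes -2.44 and -2.73).

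GFP-FIE against Ctrl shows how far the complemented line stands from the wild type. FIE transcript was 1.45 times that of Ctrl (log2 fold change 0.54 ± 0.06 SE, n = 3 per group, edgeR adjusted p = 1.08e-09). LEA7 fell from 160 to 0.241 CPM (-9.35 ± 0.10, adjusted p = 1.39e-45), LTI65 from 154 to 0.506, LEA4-5 from 33.5 to 0.191, AT3G17520 from 53.3 to 0.0494 and LTP4 from 43.4 to 0.0477. AT3G02480 (log2 fold change -7.12), AT5G35935 (-6.50) and HSFA6A (-6.29) also fell. TSPO kept 3 counts, for a ratio of Ctrl to GFP-FIE of 442 (95% counting interval 151 to 2145), and AT5G50360 kept 1 count, for a ratio of 466 (83.2 to 18431). The rises were smaller, with AT1G51270 (2.12 ± 0.09), AT1G33770 (2.02 ± 0.18), AT5G56370 (1.95 ± 0.11), AT4G16563 (22.6 to 63.9 CPM), AT3G55920 (3.47 to 9.53 CPM), AT5G05600 (6.16 to 16.8 CPM), MIOX2, an inositol oxygenase (10.2 to 36.4 CPM), XTH33 (1.82 ± 0.12), FLS2, the flagellin receptor (3.10 to 8.55 CPM) and PATL2 (75.2 to 201 CPM). Of 23 photosynthesis genes 18 rose, LHCA1 by 0.17 on the log2 scale (adjusted p = 5.00e-07, and adjusted p = 0.442 with an estimated correlation), or 19 with 1 fall adjusted over the list alone. All 4 sugar-starvation genes rose, ASN1 by 0.95 and DIN10 by 0.90 (adjusted p = 8.99e-05, and adjusted p = 0.354 with an estimated correlation). Of 12 defence genes 3 rose and 5 fell, with log2 fold changes of KIN1 at -5.57, RAB18 from 263 to 21.5 CPM and WRKY70 at -1.41. Of 24 floral genes 5 rose, FT by 1.51 and FLC by 0.63 among them, and 4 fell, SEP1 at -1.78 and FUL at -1.28 among them. Of 14 meristem genes 1 rose and 3 fell, KNAT6 among them (6 falls adjusted over the list alone), and of 11 cell cycle genes 3 fell. Camera called neither these lists (lowest adjusted p = 0.319) nor the remaining ones. In the PRC1, PRC2, ribosomal, TOR and demethylase lists 1 gene each passed, in the root list 1 (2 adjusted over the list alone), and in the embryo, pollen and seed storage lists 0 (1 embryo gene adjusted over the list alone). In all, 2893 genes rose and 3073 fell, of which 163 and 393 by at least 2-fold. Of these 393, 250 also fell at least 2-fold in amiR-fie-es, against 20.6 for independent lists, a count chosen after seeing the data. Both comparisons use the same Ctrl libraries. For these genes, Ctrl libraries that stand apart and a fall in both lines cannot be told apart.

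In amiR-fie-es and SSTS/AAAA, each against its control, many genes moved in shared directions. FIE transcript was lower in both, and the effects of FIE level and of its residues were not separated. Of the genes that rose in each, 3572 rose in both, against 1951 shared by independent lists (Fisher exact odds ratio 5.57, one-sided log10 p = -602), and 4065 fell in both, against 1938 (odds ratio 10.1, log10 p = -1044). For changes of at least 2-fold, 661 genes rose in both, against 71.1, and 444 fell, against 49.96. Others moved in opposite directions: 696 rose in amiR-fie-es and fell in SSTS/AAAA, against 1894 for independent lists, and 728 the reverse, against 1997. At 2-fold or more in both, these numbered 14, against 44.1, and 98, against 80.6. AP3, AG, FT, PI, SEP3 and SVL3 were among the shared rises. Across genes, log2 fold changes had a Pearson correlation of 0.52 and a Spearman correlation of 0.56; genes are not independent replicates. The control libraries are separate, but Ctrl and GFP-FIE are different lines. Tested directly, 9128 genes differed in effect, with 4712 higher in the SSTS/AAAA effect and 4416 lower. These p-values measure only the spread between these libraries, which was small (biological coefficient of variation 0.0255), and whether the replicates were grown apart is not stated.

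H3K27me3 in the FIE lines asks whether the mark depends on FIE and on its phosphosite residues. Peaks covered 6.40 ± 0.32 Mb (SD, n = 3) in Ctrl and 0.880 ± 0.027 Mb in amiR-fie-es, a ratio of 0.138 (90% interval 0.129 to 0.151, exact permutation p = 0.10, two-sided, the smallest that 3 against 3 libraries can give). The ratio was 0.220 for the number of peaks, 0.625 for their mean width and 0.281 for marked genes (exact permutation p = 0.10 each). Of 4913 protein-coding genes marked in all 3 Ctrl libraries, 2800 had no mark in any amiR-fie-es library and 946 kept it in all 3; where at least 50% of a gene had to be covered, 1863 lost it. FLC, marked over 3162 ± 568 bp in Ctrl, had 0 bp in amiR-fie-es. A peak of Ctrl replicate 1 at FLC lay on chromosome 5 from 3177267 to 3178785 (TAIR10, 1519 bp, fold enrichment 2.13). Other long losses were at AGL17 (2875 ± 265 bp), MEA (2760 ± 267 bp), the transcription factor gene WRKY57 (2748 bp), AT2G34110, LAC7 and CDG1. STM kept 723 of 2509 bp, with a peak of Ctrl replicate 1 on chromosome 1 from 23059197 to 23061793. FIE itself carried no H3K27me3 by this rule in any group.

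Among the lists, 12 of 24 marked floral genes lost H3K27me3 in all amiR-fie-es libraries: AG (1560 bp in Ctrl), SOC1 (1705 bp), AGL24 (2169 bp), FT (1048 bp), FLC, MAF4, MAF5, AGL17, AGL19 (2185 bp), TSF (1668 bp), CAL (1203 bp) and SEP4 (1145 bp). Of 18 marked meristem genes 3 lost it (CLV3, CUC1 and CUC3) and 12 kept it. The mark was lost at 4 of 9 root genes (COBL9, PLT2, IRT1 and CASP1), 3 of 8 defence genes (PR2, PDF1.2A and COR15A), 2 of 6 embryo regulators (LEC1 and AGL15), 1 of 12 seed storage genes (OLEO4), 1 of 5 pollen genes (MGH3), 2 of 3 PRC2 genes (MEA and FIS2) and 1 of 2 PRC1 genes (BMI1C). The 7 genes that gained a mark against Ctrl included highly expressed ones, LHCA1 (541 bp), UBQ10 (471 bp), PSBO1 (403 bp), LHCA3 (342 bp) and RBCS3B (278 bp). LHCA1 and UBQ10 gained it in GFP-FIE against Ctrl as well (419 and 446 bp). Peaks over the 100 genes with the highest Ctrl RNA covered 150 ± 23 bp per gene in amiR-fie-es and 95.6 ± 15 bp in Ctrl. Without the 200 most highly expressed genes, a choice made after seeing the data, 2 gains were counted. Leaving out any amiR-fie-es replicate raised the gains to 11 or 12, since 2 of 2 is then enough.

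**Figure D2:**
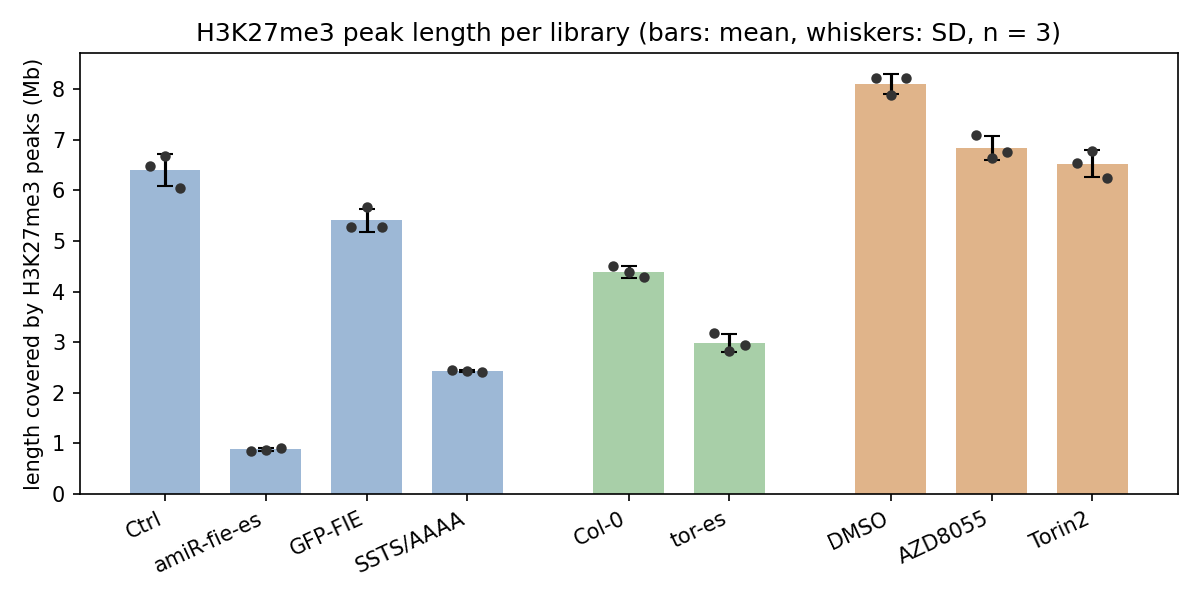
Length of the nuclear chromosomes covered by H3K27me3 peaks in each library (Mb); bars are group means, whiskers SD and points the 3 libraries of each group, coloured by experiment. Ctrl stands at 6.40 and amiR-fie-es at 0.880, GFP-FIE at 5.41 and SSTS/AAAA at 2.43, Col-0 at 4.39 and tor-es at 2.98, and DMSO at 8.11 with AZD8055 at 6.83 and Torin2 at 6.52 Mb.

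In SSTS/AAAA, H3K27me3 covered 2.43 ± 0.022 Mb against 5.41 ± 0.23 Mb in GFP-FIE, a ratio of 0.449 (90% interval 0.424 to 0.464, exact permutation p = 0.10, two-sided), with ratios of 0.573 for peak number, 0.785 for mean width and 0.627 for marked genes (exact permutation p = 0.10 each). Of 4383 genes marked in all GFP-FIE libraries, 794 lost the mark and 2428 kept it. The longest losses were at PERK11, a receptor-like kinase gene (1754 ± 297 bp), DFR, an enzyme of anthocyanin synthesis (1594 ± 161 bp), AT4G22110, AT1G62660, ANAC087 (1317 bp) and the calcium sensor CBL8 (1310 bp). Of 23 marked floral genes 22 kept the mark in SSTS/AAAA and MAF4 lost it, and of 18 meristem genes 17 kept it and CUC1 lost it. FLC shrank from 2139 to 653 bp, AG from 2190 to 412 bp and STM from 2360 to 1801 bp. In the defence, embryo, root and pollen lists 1 marked gene each lost the mark (COR15A, AGL15, PLT1 and MGH3), of 8, 5, 9 and 5, and of 12 seed storage genes 0. The 3 gains were LHCB2.1 (457 bp), MTO1 (319 bp) and LHCA3 (294 bp); 1 gain was counted without the 200 most highly expressed genes, and 5 to 10 on leaving out any SSTS/AAAA replicate or GFP-FIE replicate 1 or 2. With marking in 2 of 3 libraries enough, losses numbered 1243. GFP-FIE itself covered 0.845 of the Ctrl length (90% interval 0.790 to 0.938, exact permutation p = 0.10), 0.850 of the peak number and 0.899 of the marked genes (exact permutation p = 0.10 each) at 0.994 of the mean width (exact permutation p = 0.90), with 125 losses, such as AT1G20135 (1063 bp) and BGLU45 (868 bp), and 9 gains. Those losses rose to 218 without GFP-FIE replicate 2 and 235 without Ctrl replicate 3, and the gains to between 15 and 21 without any GFP-FIE replicate or Ctrl replicate 2.

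Genes marked in the control changed by at least 2-fold more often than unmarked genes, in both directions. Of 2138 tested genes marked in all Ctrl libraries, 442 (20.7%) rose at least 2-fold in amiR-fie-es, against 383 of 16759 unmarked genes (2.29%), a comparison chosen after seeing the data (odds ratio 4.0 within 10 classes of expression, 95% interval 3.40 to 4.71). Of genes marked in all Ctrl libraries 56.5% were not tested, against 22.5% of the other genes. A gene silent in the control passed the low-count filter only if another group expressed it. That filter raises the share of rises among tested marked genes. In SSTS/AAAA, 615 of 1946 genes marked in GFP-FIE rose at least 2-fold (31.6%), against 758 of 16971 unmarked (4.47%; odds ratio 3.74, 3.25 to 4.29). Marked genes also fell more often, at 15.4% against 3.60% in amiR-fie-es (odds ratio 3.37, 2.89 to 3.92) and 13.9% against 3.29% in SSTS/AAAA (3.04, 2.59 to 3.56). A difference in the share of rising genes between those that lost the mark and those that kept it was not detected. In amiR-fie-es, 420 of 1160 tested genes that lost the mark rose (36.2%), and 160 of 462 that kept it (34.6%; Fisher exact two-sided p = 0.566, odds ratio 1.07). In SSTS/AAAA, 166 of 357 tested genes that lost it rose (46.5%), and 524 of 1098 that kept it (47.7%; Fisher exact two-sided p = 0.714, odds ratio 0.952). Only tested genes enter these shares: in amiR-fie-es 41.4% of the 2800 that lost the mark and 48.8% of the 946 that kept it. In SSTS/AAAA these were 45.0% of 794 and 45.2% of 2428. The other genes had too few counts, so the comparison does not cover them. A gene counted as keeping the mark if it still met the rule for marked genes, however much shorter its mark was. In SSTS/AAAA, AG (2190 to 412 bp) and FLC (2139 to 653 bp) counted as kept, and their RNA rose. STM counted as kept in amiR-fie-es (2509 to 723 bp). The comparison therefore cannot show whether a shortened mark goes with a rise in RNA. With at least 50% of a gene covered as the rule, the odds ratios turned to 0.807 and 1.19, neither past the threshold, and with stricter peaks the SSTS/AAAA value turned to 1.2. TLP5, FT, AG, CER4, AT4G05470, BGLU45, GATA13, UMAMIT23, NIT2 and AT5G39890 lost the mark and rose in amiR-fie-es. TLP5, the transporter gene UMAMIT33 (1.14 to 41.9 CPM), AT2G43140, NAC047, BAM5 (0.567 to 11.9 CPM), AT5G39890, the galactosidase gene BGAL4 (7.86 to 125 CPM), AT5G10760, AT3G27025 and AT5G60760 did so in SSTS/AAAA.

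Silencing of TOR in 7-day-old seedlings tests whether the mark depends on the kinase. H3K27me3 covered 2.98 ± 0.18 Mb (SD, n = 3) in tor-es and 4.39 ± 0.12 Mb in Col-0, a ratio of 0.678 (90% interval 0.626 to 0.744, exact permutation p = 0.10, two-sided, the smallest possible). Peak number was 0.782, mean width 0.869 and marked genes 0.798 of those in Col-0 (exact permutation p = 0.10 each). Genes that lost the mark included CYP714A1 (1524 ± 255 bp in Col-0), ICL, the isocitrate lyase of the glyoxylate cycle (1337 ± 48 bp), the seed oil-body gene OLEO4 (1013 bp), AGO9 (984 bp), DFR (953 bp) and LTI65 (927 bp). FLC shrank from 1604 to 408 bp and STM from 1765 to 1069 bp, and AG stood at 612 and 557 bp. Of 24 marked floral genes MAF4 lost the mark, of 18 meristem genes CUC1, and the embryo regulator LEC1 lost it too. Of 4003 genes marked in all Col-0 libraries, 279 lost the mark, 2866 kept it and 9 others gained it, AT5G05250 (583 bp) and AGO10 (265 bp) among them. Losses rose to 426 without tor-es replicate 1, to 602 where marking in 2 of 3 libraries was enough, and to 443 where 1 kb on each side of a gene was included. Gains rose to between 16 and 30 without any tor-es replicate or Col-0 replicate 1 or 3.

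H3K9me2, a mark of transposons and pericentromeric chromatin, covered 0.112 ± 0.0061 Mb in tor-es and 0.127 ± 0.015 Mb in Col-0, a ratio of 0.884 (90% interval 0.748 to 1.03, exact permutation p = 0.20, two-sided), with ratios of 0.852 for peak number (exact permutation p = 0.20), 1.04 for mean width (exact permutation p = 0.10) and 0.875 for marked genes (exact permutation p = 0.60). The change in H3K27me3 was larger than that in H3K9me2 by -0.38 on the log2 scale, a difference that did not pass (exact permutation p = 0.155, two-sided, 400 arrangements). It passed for peaks with −log10 q of at least 10, at -1.24 (exact permutation p = 0.035). Of 22 genes marked in all Col-0 libraries, AT5G56920 and AT3G50320 lost H3K9me2, and SWN, a PRC2 methyltransferase gene (651 ± 140 bp), and AT2G07669 gained it. These counts reached 4 or 5 on leaving out any Col-0 replicate for losses, and tor-es replicate 1 or Col-0 replicate 1 for gains. Of 3890 pseudogenes, 35 were marked in all Col-0 libraries and 22 in all tor-es libraries.

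AZD8055 and Torin2 are inhibitors of the TOR kinase and were given at the same dose, 10 µM, for 3 days. H3K27me3 covered 6.83 ± 0.23 Mb (SD, n = 3) with AZD8055 and 8.11 ± 0.19 Mb with DMSO, a ratio of 0.843 (90% interval 0.807 to 0.9). With Torin2 it covered 6.52 ± 0.27 Mb, a ratio of 0.804 (0.760 to 0.860). Exact permutation p was 0.10 for each, two-sided. AZD8055 nevertheless gave more peaks than DMSO (ratio 1.09) and more marked genes (1.08), narrower in mean width (0.776), whereas Torin2 gave fewer peaks (0.883) and fewer marked genes (0.881), also narrower (0.913), each with exact permutation p = 0.10. Under AZD8055, FIP37, a subunit of the RNA adenosine methylation complex, lost 2492 ± 87 bp, and the root nitrate transporter gene NRT1.5 lost 1282 bp, BHLH92 1085 bp and AT3G05400 1565 bp. FIP37 carried 0 bp of H3K27me3 in Col-0 of the same age, so its mark was seen in the inhibitor experiment alone. Under Torin2, LTI65 lost 1220 ± 114 bp, AT3G10815 1267 bp, UGT84A2 1119 bp, and ETP1 and DREB26 lost the mark as well. FLC shrank from 2455 bp with DMSO to 1131 bp with AZD8055 and 1790 bp with Torin2, AG from 1909 to 568 and 1282 bp, and STM from 2362 to 1306 and 2253 bp. TOR itself was marked over 1314 ± 296 bp with DMSO, 844 ± 236 bp with AZD8055 and 631 ± 197 bp with Torin2, and over 0 bp in the other experiments. With DMSO this was 7.40% of the gene, and a peak of DMSO replicate 1 there had a fold enrichment of 1.87 and −log10 q of 2.69.

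Of 7321 genes marked in all DMSO libraries, 348 lost the mark with AZD8055 and 257 with Torin2. Only 116 of the 348 and 25 of the 257 were also marked in all Col-0 libraries, of the same age. Gains numbered 445 with AZD8055, among them AT3G28780 (1455 bp), the photoreceptor gene ZTL (928 bp), ADR1-L1 (900 bp) and PRORP1 (882 bp), and 7 with Torin2, among them OPS (294 bp) and NAF1. Of the 445 genes gained with AZD8055, 302 were unmarked in every Torin2 library and 5 were marked in all 3. In all 3 Col-0 libraries 0 of the 445 were marked, and in all 3 Ctrl libraries 0. With peaks of −log10 q of at least 5, AZD8055 had 463 losses and 168 gains, and with 50% of the gene covered 608 and 35, so that the balance turned to more losses than gains. Its gains rose to 718 and 719 without AZD8055 replicate 2 or 3, and Torin2 losses rose to 436 without Torin2 replicate 2, with gains of 14 to 36 without any Torin2 or DMSO replicate. Among the lists, MAF4 (floral), CUC1 (meristem), CDKB1;1 (cell cycle) and 2 of 9 defence genes (PDF1.2A and WRKY70) lost the mark with AZD8055, and WRKY70 with Torin2. All 23 photosynthesis, 7 ribosomal and 4 sugar-starvation genes were marked with DMSO and with AZD8055. In each group of this experiment 99 of the 100 genes with the highest Ctrl RNA carried peaks in all 3 libraries, against 2 in the Col-0 group of the same age.

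Compared with each other, Torin2 covered 0.955 of the AZD8055 length (90% interval 0.881 to 1.02, exact permutation p = 0.30, two-sided). Torin2 gave fewer peaks (ratio 0.812) that were wider (1.18), and fewer marked genes (0.814), each with exact permutation p = 0.10. On sequence covered in all 3 Col-0 libraries, a choice made after seeing the data, the direction turned. The ratio of Torin2 to AZD8055 was 1.19 there (1.16 to 1.2), with AZD8055 at 0.794 of DMSO (0.782 to 0.807) and Torin2 at 0.941 (0.925 to 0.956), each with exact permutation p = 0.10. It turned also for stricter peaks, to log2 ratios of 0.026 and 0.11. Between the inhibitors 591 genes had the mark in all AZD8055 and no Torin2 libraries, such as EIN3 (1381 bp), BAM1 (1259 bp) and PAP26, and 114 the reverse, such as FIP37 (1795 bp), MYB122 (1096 bp) and BNQ3 (774 bp). The first count rose to 918 and 896 without AZD8055 replicate 2 or 3, and the other to 180, 177 and 185 without Torin2 replicate 3 and AZD8055 replicates 1 and 3. The direction also differed along the chromosomes. In the 12 bins of 1 Mb richest in H3K9me2 in Col-0, of 121, AZD8055 covered 1.51 times the DMSO length (90% interval 1.40 to 1.61), Torin2 covered 0.952 of it (0.887 to 1.02), and Torin2 covered 0.630 of the AZD8055 length (0.580 to 0.691). The rise lay in 9 of these bins, where AZD8055 covered 2.92 times the DMSO length (2.65 to 3.18) and Torin2 1.22 times (1.17 to 1.31), each with exact permutation p = 0.10; the 9 were chosen on the AZD8055 values. With AZD8055, bins with little H3K27me3 rose on both sides of the cut for H3K9me2-rich bins. Those below the cut still carried 1.37 to 1.84 kb of H3K9me2 in Col-0, against 1.95 kb in the lowest rich bin. Little H3K27me3 and H3K9me2 were therefore not fully separated here. In the 12 bins with the least H3K27me3 in Ctrl, also chosen after seeing the data, AZD8055 covered 2.72 times the DMSO length (2.46 to 3.01), in the 3 of these that are not H3K9me2-rich 2.29 times (2.05 to 2.65), and in the 3 H3K9me2-rich bins outside them 0.916 of it (0.872 to 0.974), each with exact permutation p = 0.10; Torin2 covered 1.12 times the DMSO length in the 12 bins and 0.915 in the 3 that are not H3K9me2-rich. For peaks with −log10 q of at least 10, AZD8055 covered 1.2 times the DMSO length in the 9 bins (1.07 to 1.33), 0.763 times over all 12 rich bins, 1.08 times in the 12 bins with the least H3K27me3 (0.961 to 1.17) and 0.804 times in the 3 of these that are not H3K9me2-rich (0.655 to 0.930).

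**Figure D3:**
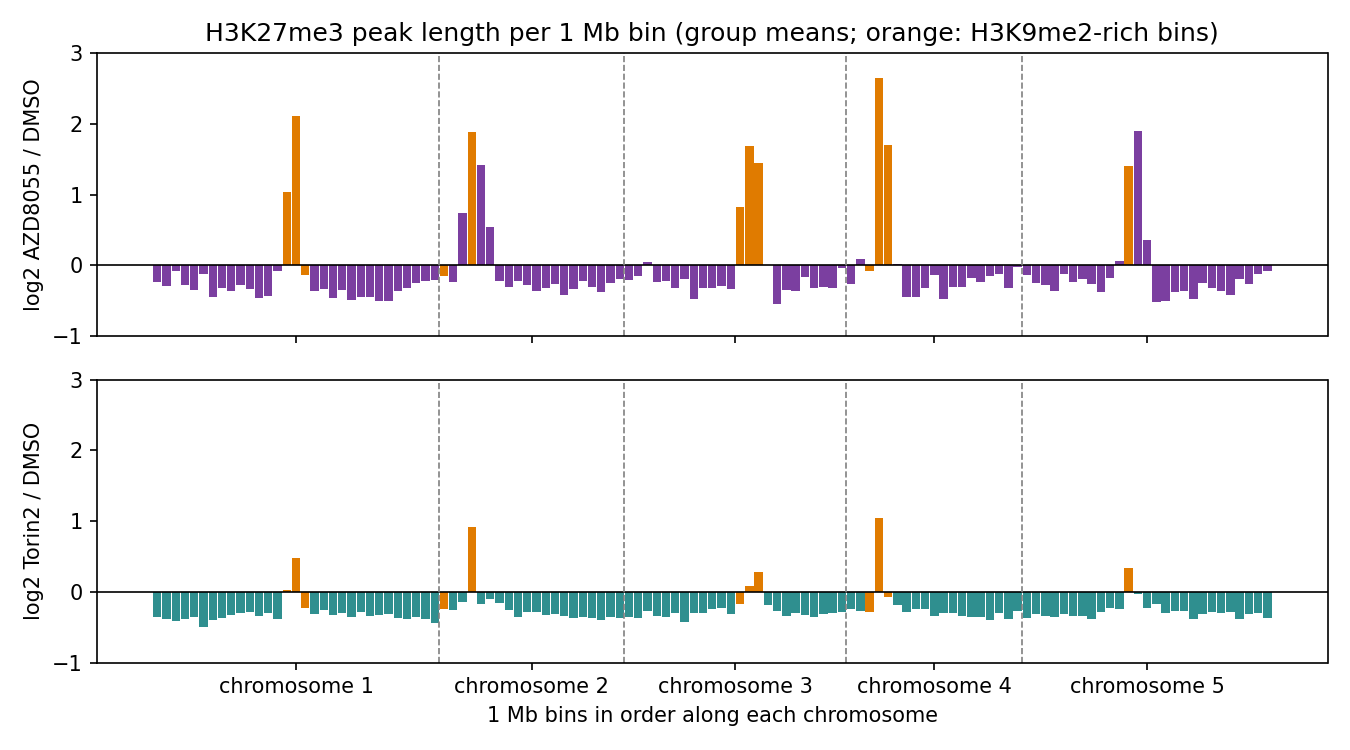
Log2 ratio of H3K27me3 peak length to DMSO in 121 bins of 1 Mb, group means of 3 libraries, for AZD8055 (top) and Torin2 (bottom); orange bars are the 12 bins richest in H3K9me2. AZD8055 lies above 0 in 9 of the 12 orange bins and 9 of the 109 others, Torin2 in 7 and 0.

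Losses of H3K27me3 overlapped between experiments. Genes were not matched for the strength or length of their control peaks. Weak or short peaks that drop out wherever less is called could therefore give part of each overlap. The p-values treat genes as independent replicates, which they are not. Of genes marked in both controls, 663 lost the mark in both amiR-fie-es and SSTS/AAAA, against 361 for independent lists (Fisher exact odds ratio 19.2, one-sided p = 2.9e-158). Genes that lost the mark in tor-es lost it in amiR-fie-es in 220 cases, against 117 (Fisher exact odds ratio 10.1, one-sided p = 6.0e-46), and in SSTS/AAAA in 86, against 23.1 (7.01, p = 8.6e-32); DFR was lost in both tor-es and SSTS/AAAA. For tor-es with AZD8055 the shared losses were 49, against 7.46 (12.9), with MAF4 and CUC1 in both, and for tor-es with Torin2 21 of 25, against 1.61 (83.1), with LTI65 in both. For peaks with −log10 q of at least 5 these 2 overlaps were smaller, with 29 shared losses for AZD8055 (odds ratio 7.85) and 9 of 17 for Torin2 (10.5). The inhibitors shared 98 losses, against 12.2 for independent lists (16.8). They share DMSO libraries, and unchanged groups simulated against those gave a mean of 19.8 shared losses and at most 33. Each simulated list held a mean of 59.6 losses, against 348 with AZD8055 and 257 with Torin2. Lists so much shorter cannot show how far the 98 exceed the effect of shared controls. The 3 DMSO libraries were not divided between the inhibitors for this overlap, so part of the excess may come from them. Over amiR-fie-es, SSTS/AAAA and tor-es together, the mean log2 ratio of covered length was -1.53 (exact stratified permutation p = 0.00025, two-sided, the smallest that 8000 arrangements can give).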

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

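The test of the difference of effects, the tests of other splits of the libraries and the length of strong peaks over all 12 H3K9me2-rich bins were fixed beforehand; the other tests here were chosen after the result was seen.

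The fall of H3K27me3, with FLC, AG and AGL17 among the genes that lost it or shrank in amiR-fie-es, was set against fewer reads, which would shorten peaks of equal strength alike. Control peaks over the 100 genes with the highest Ctrl RNA were compared with other control peaks of the same strength and width. In amiR-fie-es 54.9% of the length of the former stayed covered (46.1% to 61.3%, n = 3) and 4.50% of the matched peaks, where the Ctrl libraries covered 57.7% and 62.4% of each other's. In SSTS/AAAA the shares were 54.6% (49.9% to 59.3%) and 18.3%, against 58.7% and 61.1% among GFP-FIE libraries, and with AZD8055 92.7% (91.2% to 94.2%) and 75.5%, against 92.4% and 89.7% among DMSO libraries. These values argue against fewer reads as the whole cause in those 3 comparisons. With Torin2 the shares were 87.2% and 81.5%, between both predictions, and in tor-es 35.7% and 33.9% on 8.33 peaks per library, so there fewer reads and loss of the mark cannot be told apart.

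Weaker capture with more background is a separate matter, since it would lower marked peaks and leave or raise peaks over highly expressed genes. Over those 100 genes amiR-fie-es covered 1.57 times the Ctrl length (90% interval 1.17 to 2.15), as this explanation needs. The same ratio was 1.21 in SSTS/AAAA (0.930 to 1.40), 1.81 in tor-es (0.388 to 4.79, on 2 genes marked in Col-0), 1.01 with AZD8055 and 0.946 with Torin2 (0.931 to 0.969). In those 4 comparisons weaker capture and loss of the mark cannot be told apart, because the ratio overlaps 1, rests on too few genes, or runs on genes nearly all marked in DMSO. A loss of the mark with less FIE and weaker capture both stay open in amiR-fie-es, as input and depth are unknown.

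AZD8055 raised H3K27me3 peak length in H3K9me2-rich bins, while the length fell in the other bins (log2 ratio -0.28). The number of peaks rose in both, to 2.37 times DMSO in the rich bins and 1.05 times in the others (exact permutation p = 0.10 each), so more calling over the whole genome and a change in the rich bins cannot be told apart. By these classes of bins the rise went with little H3K27me3. Of the 12 bins with the least H3K27me3 in Ctrl, the 3 that are not H3K9me2-rich rose too (log2 ratio 1.2, 2.05 to 2.65 as a ratio), though not in strong peaks (0.655 to 0.930). The 3 H3K9me2-rich bins outside those 12 fell (0.872 to 0.974). However, the 3 that are not rich carried 1.37 to 1.84 kb of H3K9me2 in Col-0, against 1.95 kb in the lowest rich bin. Little H3K27me3 and H3K9me2 were therefore not fully separated. Over all 12 rich bins the log2 ratio was -0.39 for peaks with −log10 q of at least 10, the value that weak peaks near the threshold predict. In the 9 bins that rose, strong peaks were tested with bins chosen by 1 AZD8055 and 1 DMSO library and measured in the others. The mean log2 ratio was 0.23, with every AZD8055 library above in 8 of 9 choices, but in 1 choice 10 bins were taken and the ratio turned to 0.934, so weak peaks as the whole cause and a gain of strong ones cannot be told apart there. Signal moving there wherever the mark falls elsewhere is argued against by amiR-fie-es, at -0.80 in the 9 bins, and by SSTS/AAAA, at -0.31. Over all 12 rich bins Torin2 covered 0.952 of the DMSO length and tor-es 0.892 of the Col-0 length. In the 9 bins, both stood above their controls. Because the 9 were chosen against DMSO, they were chosen again with each DMSO library alone, which gave the 9 bins each time, and Torin2 was set against the other DMSO libraries: the mean log2 ratio was 0.28, with ratios of 1.19 to 1.23 and every Torin2 library above them. In tor-es the log2 ratio was 0.23 (ratio 1.17, 1.05 to 1.32), but its strong peaks stood at 0.02 (0.896 to 1.17 as a ratio). GFP-FIE, in which TOR was not reduced, stood at a log2 ratio of 0.14 against Ctrl in these bins (0.989 to 1.25 as a ratio). In the 3 low bins that are not H3K9me2-rich, Torin2 (0.871 to 0.9996 as a ratio) and tor-es (0.797 to 0.922) fell. A gain shared by the treatments that reduce TOR in the 9 bins therefore stays open beside weak peaks near the threshold and more background, which was not tested in these bins.

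The 6 neighbouring genes from AT4G22485 to AT4G22520 were 111 to 300 times lower in SSTS/AAAA than in GFP-FIE RNA, while AT4G22470 and AT4G22530 on either side stood at 0.350 and 2.02 CPM in GFP-FIE and 0.789 and 3.89 in SSTS/AAAA. Spread of H3K27me3 over the block is argued against as far as called peaks show: its covered length in SSTS/AAAA was 0.701 of that in GFP-FIE (1357 ± 177 and 1935 ± 26 bp, n = 3). That ratio does not allow for the fall over the whole genome, to 0.449. However, AT4G22485, AT4G22490, AT4G22513 and AT4G22520 had 0 bp in SSTS/AAAA. A deletion in this line could remove the transcripts. ChIP peaks still covered 1339 bp of AT4G22505 in the 3 SSTS/AAAA libraries, but reads of similar copies could be placed there and their handling is not stated, so a deletion and silencing by another route cannot be told apart. No biological explanation beyond the mark was tested.

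The effects of amiR-fie-es and of SSTS/AAAA, each against its own control, differed in 9128 genes by a test of the difference itself. Over the 12 rich bins every AZD8055 library stood above the DMSO mean and every Torin2 library below it, at a mean of -0.072 for Torin2; this difference of directions was not tested beyond the ratio of Torin2 to AZD8055, 0.630 (exact permutation p = 0.10). Chloroplast peaks numbered 8.33 per library in tor-es and 2.67 in Col-0, outside the nuclear comparison (exact permutation p = 0.10). Mitochondrial peaks numbered 31.7 with AZD8055 and 23.0 with Torin2, against 14.7 with DMSO (exact permutation p = 0.10 each). Pseudogenes marked by H3K27me3 numbered 631 with AZD8055 and 133 with DMSO (exact permutation p = 0.10), and 157 with Torin2.

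Other splits of 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05, and 1 split, the real one, gave the most genes in each comparison. In RNA the real splits called 11873 genes for amiR-fie-es against Ctrl, 13137 for SSTS/AAAA against GFP-FIE and 5966 for GFP-FIE against Ctrl, and the highest other split 0 each. For lost and gained marks together the real and highest other values were 2807 and 3 for amiR-fie-es, 797 and 13 for SSTS/AAAA, 134 and 42 for GFP-FIE against Ctrl, and 288 and 39 for tor-es. They were 793 and 51 for AZD8055, 264 and 67 for Torin2, 705 and 55 for Torin2 against AZD8055, and 4 and 2 for H3K9me2. For the difference of effects, 1 of 50 splits drawn from 200, the real one, gave 9128 genes and the highest other 6465. That cannot exclude chance and says nothing on whether the effects are equal, because dividing the libraries of a comparison removes its effect. The real split was the only 1 drawn that divided neither comparison. The 42 splits that divided both comparisons called 0, the 3 that left SSTS/AAAA and GFP-FIE undivided 6332 to 6465, and the 4 that left amiR-fie-es and Ctrl undivided 1297 to 2993.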

How the results depend on the processing

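The alternatives on sequence covered in Col-0, on 1 kb on each side of genes, on the 200 most highly expressed genes, on bins, on GFP-FIE as the control for amiR-fie-es and Ctrl for SSTS/AAAA, and for the difference of effects those on 1 CPM in 3 libraries and on leaving out each library, were chosen after seeing the data. Counting a gene with 1 kb upstream was not run, because the gene table gives no strand; 1 kb on each side stands in its place. Peak lists limit what depth can show: without reads, a mark below the calling threshold and an absent one are not told apart. Among the alternatives of the main results 342 gave the same direction and side of the threshold (for counts, within 1.5 times), 99 moved further, 7 reversed and 1 became stronger. For the 438 pairs of a named gene and a comparison, 5109 of 5225 values stayed on the same side, 90 became weaker, 26 stronger and 0 reversed. RLE in place of TMM, either low-count filter, and leaving out any RNA library kept every RNA count within 1.5 times, as did fits of only the groups compared for the 3 comparisons of groups (the difference of effects needs all 4), and DESeq2, with 5151 higher and 5320 lower genes for amiR-fie-es, 5844 and 6009 for SSTS/AAAA, 2209 and 2474 for GFP-FIE and 7587 for the difference. In edgeR the difference ranged from 8637 to 8931 genes without each library. Organelle genomes changed no covered length beyond its spread, and for the overlap of at least 1 bp only gains of H3K9me2 moved, to 1. The cause was not tested where a value below moved, unless the setting's construction gives it.

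With a 2-fold minimum, which leaves fewer genes by construction, amiR-fie-es had 929 higher and 1053 lower genes, SSTS/AAAA 1534 and 951, and GFP-FIE 163 and 393. Of 45 list tests, camera called 10, 2 of them with an estimated correlation, and fry, which tests a list on its own, called 34. In amiR-fie-es, camera and fry differed in sign for the meristem list (median 0.14, fry down) and the TOR list. The replicate numbers do not pair the libraries: in RNA, same-numbered deviations correlated between -0.03 and 0.04 across genes, and not every library was closest to its own number. With the replicate block, counts were 5844 and 5984 for amiR-fie-es, 6636 and 6447 for SSTS/AAAA, 2852 and 3039 for GFP-FIE against Ctrl and 9066 for the difference, the overlap odds ratio 5.59 and the lists called 10. Blocked log2 ratios of covered length were -2.86 for amiR-fie-es, -1.15 for SSTS/AAAA, -0.24 for GFP-FIE, -0.56 for tor-es, -0.25 for AZD8055, -0.31 for Torin2, -0.07 for Torin2 against AZD8055 and -0.18 for H3K9me2 (exact sign-flip p no lower than 0.25 by construction), with -0.38 between the marks and -1.53 stratified; the block changed no call.

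Stricter peaks moved covered length, as log2 ratios. With −log10 q of at least 5 they were -3.38 for amiR-fie-es, -1.32 for SSTS/AAAA, -0.74 for tor-es, -0.42 for AZD8055, -0.39 for Torin2 and 0.026 for Torin2 against AZD8055, a reversal. With at least 10 they were -4.13, -1.66, -1.22, -0.68, -0.57 and 0.11, and H3K9me2 turned to 0.020; the difference between the marks grew to -1.24 and passed the threshold (exact permutation p = 0.035). On sequence covered in Col-0, AZD8055 stood at -0.33, Torin2 at -0.088 and Torin2 against AZD8055 at 0.25, a reversal.

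Counts of genes were the least stable, above all small ones. With −log10 q of at least 5, gains were 2 for amiR-fie-es, 4 for GFP-FIE, 168 for AZD8055 and 3 for Torin2, genes lower in Torin2 than AZD8055 349, and H3K9me2 losses 0. With 50% of the gene covered, losses were 1863 for amiR-fie-es, 78 for GFP-FIE, 608 for AZD8055, 100 for Torin2 against AZD8055 and 0 for H3K9me2, and gains 1 for amiR-fie-es, 0 for SSTS/AAAA, 3 for tor-es, 35 for AZD8055, 1 for Torin2, 216 for Torin2 against AZD8055 and 0 for H3K9me2. With marking in 2 of 3 libraries enough, an easier rule, losses and gains were 1243 and 18 for SSTS/AAAA, 331 and 36 for GFP-FIE, 602 and 54 for tor-es, 582 and 1156 for AZD8055, 574 and 83 for Torin2, 1425 and 273 for Torin2 against AZD8055 and 10 and 6 for H3K9me2, and gains 21 for amiR-fie-es. With 1 kb on each side, tor-es losses were 443, and gains 14 for GFP-FIE, 16 for Torin2 and 1 for H3K9me2. Without the 200 genes highest in Ctrl RNA, gains were 2 for amiR-fie-es and 1 for SSTS/AAAA. The odds ratio of loss and RNA rise reversed to 0.807 in amiR-fie-es (Fisher exact two-sided p = 0.461) and 1.19 in SSTS/AAAA (p = 0.340) with 50% of the gene, and to 1.2 in SSTS/AAAA (p = 0.180) with −log10 q of at least 5, none past the threshold.

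All 6 overlaps of lost marks stayed past the threshold in each setting run for them. These were the main rule, at least 1 bp of the gene, at least 50% of it, and peaks with −log10 q of at least 5. Odds ratios ranged from 19.1 to 120 for amiR-fie-es with SSTS/AAAA, 6.22 to 15.7 for tor-es with amiR-fie-es and 5.29 to 7.05 for tor-es with SSTS/AAAA. They ranged from 9.03 to 16.8 for AZD8055 with Torin2, 6.07 to 12.9 for tor-es with AZD8055 and 10.5 to 83.1 for tor-es with Torin2. The last rests on few genes, with 21 shared losses of 25, and 9 of 17 with −log10 q of at least 5.

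Leaving out a library makes the rule easier, since 2 of 2 or 0 of 2 is then enough. Without each replicate, losses ranged from 164 to 235 for GFP-FIE, 358 to 426 for tor-es, 344 to 436 for Torin2, 710 to 918 for Torin2 against AZD8055 and 2 to 5 for H3K9me2. Gains ranged from 7 to 12 for amiR-fie-es, 3 to 10 for SSTS/AAAA, 12 to 21 for GFP-FIE, 13 to 30 for tor-es, 514 to 719 for AZD8055, 14 to 36 for Torin2, 150 to 185 for Torin2 against AZD8055 and 2 to 5 for H3K9me2.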

Other observations

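The tests over bins named here were chosen after the results were seen. Most of the H3K9me2-rich bins, those with little H3K27me3, differed from the other bins. Of the 109 bins of 1 Mb outside the H3K9me2-rich ones, group means stood above the control in 9 with AZD8055, 0 with Torin2 and 1 in tor-es, but of the 12 rich bins in 9, 7 and 7. In 9 rich bins the fall of H3K27me3 in amiR-fie-es was also smaller, with 0.576 of the Ctrl length covered (0.500 to 0.648) against 0.132 in the bins outside. In SSTS/AAAA those ratios were 0.806 and 0.443. The 3 rich bins not among the 12 with the least H3K27me3 in Ctrl stood at 0.186 in amiR-fie-es and 0.506 in SSTS/AAAA, and the 3 among these 12 that are not rich at 0.170 and 0.495.

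Some single genes showed the mark in few groups. AT3G20730, the neighbour of FIE, carried 528 ± 123.3 bp (SD, n = 3) of H3K27me3 in GFP-FIE and 0 bp in all other groups, SSTS/AAAA included. FIP37 carried 2492 ± 87 bp with DMSO and 1795 ± 557 bp with Torin2, and 0 bp with AZD8055 and in the other experiments. SWN carried 651 ± 140 bp of H3K9me2 in tor-es and 0 bp in Col-0. Of the 445 genes that gained H3K27me3 with AZD8055, 16 (3.60%) lay in the rich bins, which hold 2.91% of all genes.

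Peaks over highly expressed genes were counted in each experiment, without separating the experiment from how much was called in it. Of the 100 genes with the highest Ctrl RNA, peaks marked 11 in all Ctrl libraries, 18 in amiR-fie-es, 17 in GFP-FIE, 21 in SSTS/AAAA, 2 each in Col-0 and tor-es, and 99 each with DMSO, AZD8055 and Torin2.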
